A study of Mus musculus with 12 samples.

How the data were processed

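Total RNA of sorted mouse muscle progenitors was measured in 12 libraries, 3 in each of the teratoma, transplant, embryo and adult groups. Per the labels' protocols, tissue was digested with collagenase II and dispase, cells were sorted by flow cytometry, RNA was purified on RNeasy columns with DNase I treatment, and libraries were made with the SMARTer Stranded Total RNA-seq Pico kit. Enzymatic dissociation before a sort can itself induce immediate early and heat shock genes. The submitters' processing notes name CASAVA 1.8.2, TopHat 0.7, Cufflinks 2.2.1.0, Partek and the mouse build mm10, without roles, and the versions are given as written there. Read counts, mapping rates, the gene annotation and the use of strand are not given in the sources used here. The authors deposited 1 table of FPKM values per gene symbol and library, per the file headers.

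The table held 23746 entries, of which 462 repeated one of 240 symbols. Values of repeated symbols were summed, leaving 23284 symbols. All 12 columns matched 1 library each by title. Depth could not be recovered from the values, so no interval or detection floor is given, and an exact 0 can be a failed estimate. With this total-RNA kit small and ribosomal RNA took from 39.0% to 97.7% of the FPKM sum. Median-ratio factors computed from the FPKM ran from 0.796 (adult replicate 2) to 1.30 (embryo replicate 3). Genes with near-identical copies, such as the globins Hba-a1 and Hba-a2, replication histones and Hspa1a and Hspa1b, can share reads and are uncertain singly.

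Tests ran in R 4.3.3 with limma 3.58.1 on log2(FPKM + 1). Genes with at least 1 FPKM in at least 3 libraries were kept (12699 genes). One linear model over the 4 groups used all 12 libraries (8 residual degrees of freedom), with an intensity trend in the empirical Bayes step. The 6 pairwise comparisons were each adjusted by Benjamini-Hochberg over all tested genes, and a gene was called at an adjusted p under 0.05. Positive changes are higher in the group named before "against". Gene lists, 44 in number, covered muscle stages, cell cycle, imprinting, Hox position, matrix, stress, metabolism, signalling and markers of other cell types. The 37 with at least 5 tested members were tested with camera (preset correlation 0.01, adjusted over the lists of a comparison), and again with a correlation estimated from the data. List counts are given over all genes tested and adjusted over the list alone. Ribosomal protein genes were taken by symbol pattern, which also takes a few S6 kinases, and were run again without these.

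Named genes followed a rule. The regulators Pax7, Pax3, Myf5, Myod1, Myog and Nfix and the sort genes Itga7, Vcam1, Pecam1 and Ptprc belong to every comparison, though Ptprc did not pass the filter and is given once. The 4 main comparisons add the 5 higher and 5 lower genes with the largest change, among called genes whose 2 groups of libraries do not overlap (which 10% of unchanged genes do by chance with 3 against 3) and whose higher mean is at least 5 FPKM. Predicted, small RNA, mitochondrial, ribosomal protein and histone genes were left out of that choice. Up to 4 called members of each called list and up to 2 of each other list follow, ranked by size of change. The other 2 comparisons take 3 higher and 3 lower genes. Hprt, Xist and 4 Y-linked genes served as origin checks. This rule, the lists, the tests and the alternatives were fixed before the data were examined, except where stated. Igf2 in teratoma against embryo, Rpl34, Taf10 and the most abundant fibroblast genes were named after their values were seen.

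The axis position projected each library on the difference between embryo and adult means. For teratoma and transplant libraries, the axis was computed from 2 libraries of each, its ends from the library left out, and the mean over all 9 choices is given. An embryo or adult library was itself kept out of both the axis and the ends, so fewer libraries of its group and fewer choices remained for it. Alternatives were a pseudocount of 0.1, no filter, a filter at a mean of 5 FPKM, median-ratio scaling, quantile normalization, fitting only the 2 groups compared, library quality weights, the replicate number as a block, a log2 change of at least 1, and leaving out each library in turn. Alternatives chosen after seeing the data set isolated zeros as missing, left out small and ribosomal RNA genes, left out cell cycle genes from the axis, and removed kinases from the ribosomal list. The steps were tested on simulated data. For teratoma against embryo, 42% of 100 genes changed by 1 on the log2 scale and 88% of 100 changed by 2 were recovered, and 10 of 11944 unchanged genes were called. The changed genes had a mean log2(FPKM + 1) above 2. Noise was independent between genes and drawn around a mean common to all groups, without scaling differences or failed estimates. These rates may therefore not carry over to the real data. Coordinates came from GENCODE M21 on the same build, matched by symbol for 11573 of the tested genes.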

Results

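RNA-seq was available for 12 libraries of mouse muscle progenitors in 4 groups of 3. The cells had been isolated by flow cytometry on the adhesion molecules α7-integrin and VCAM, leaving out cells with the endothelial antigen CD31 or the leukocyte antigen CD45. The teratoma group came from 3-week-old teratomas, mixed-tissue tumours that pluripotent stem cells form after injection. The transplant group was isolated again from tibialis anterior muscle 1 month after teratoma-derived cells had been transplanted. The embryo group came from whole embryos at E14.5, and the adult group from hindlimbs of 8-week-old males, where such cells are the satellite cells, the resident stem cells of muscle. The series title is about obtaining muscle stem cells by way of pluripotent ones. The comparisons therefore set the native stages against each other, each stem-cell-derived group against the native ones, and the transplant against the teratoma group. Values were deposited as FPKM, so the read depth was unknown. Between 9495 genes (adult replicate 1) and 12000 (teratoma replicate 1) reached 1 FPKM. The design text calls the 3 libraries of a group biological replicates and says nothing of separate animals, so p-values measure the spread between these samples. Values below are mean FPKM ± SD (n = 3), and changes are on the log2(FPKM + 1) scale, which understates those of low genes. For a group with any library listed at 0, the 3 values are given singly.

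Libraries of one group resembled each other more than those of other groups. Pearson correlations across genes averaged 0.909 within teratoma, 0.917 within transplant, 0.882 within embryo and 0.943 within adult. Between groups they ran from 0.665 for embryo and adult to 0.835 for teratoma and transplant. Embryo replicate 2 stood apart: 74 genes were listed at 0 there while both group mates were at 5 FPKM or more, against 6 to 27 in the other libraries. Zeros of this kind reached housekeeping genes, such as Rpl34 and Taf10, listed at 0 in transplant replicate 3 only, so a 0 is given as listed. Small and ribosomal RNA took 39.0% (embryo replicate 2) to 97.7% (adult replicate 2) of the FPKM total.

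**Figure D1:**
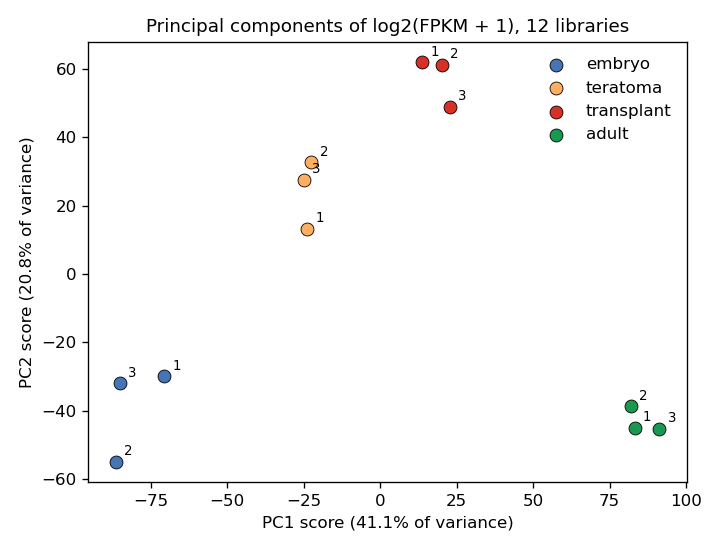
Principal components of log2(FPKM + 1) over the tested genes, with 1 point per library coloured by group. The first component (41.1% of the variance) runs from embryo through teratoma and transplant to adult. The other axis (20.8%) separates both stem-cell-derived groups (13.3 to 62.0) from both native groups (-55.0 to -29.9).

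The genes behind the sort were read first. Itga7, which encodes α7-integrin, stood at 43.9 ± 4.02 in teratoma, 43.1 ± 10.9 in transplant, 10.4 ± 0.577 in embryo and 62.0 ± 0.506 in adult. Vcam1 was at 89.7 ± 27.2, 82.7 ± 12.3, 53.0 ± 4.48 and 102 ± 16.7 in the same order. Of the genes for the excluded antigens, Pecam1 (CD31) was at 7.08 ± 2.22, 1.96 ± 0.485, 3.68 ± 4.07 and 3.34 ± 1.35. Ptprc (CD45) did not pass the expression filter and was at most 1.44 FPKM, in teratoma replicate 3. All 4 groups carry the same strain label, 129P2/OlaHsd. The labels name no host strain for the transplants, so whether host and donor differ in strain is not known. Hprt, the purine salvage enzyme (chromosome X from 52988137 to 53021659 in mm10), was at 0.579, 1.69 and 1.45 in the teratoma libraries and 2.02, 0.323 and 0.152 in the transplant libraries, against 32.0 ± 10.6 in embryo and 44.5 ± 12.3 in adult. Y-linked transcripts were present in each library but embryo replicate 2, where Ddx3y, Eif2s3y, Kdm5d and Uty were all listed at 0. Ddx3y was at 13.8 ± 2.58 in teratoma, 9.16 ± 3.23 in transplant, 15.5, 0 and 13.5 in embryo and 43.9 ± 6.40 in adult. Xist, the noncoding RNA of the inactive X chromosome, was listed at 0 in all 3 embryo libraries, also where the Y genes were, and at 2.07 ± 0.373 in teratoma, 0.488 ± 0.0121 in transplant and 0.0957, 0.206 and 0 in adult.

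Muscle regulators differed between the groups in level and in order. Pax7, the satellite cell transcription factor (chromosome 4 from 139737062 to 139833528), was at 23.1 ± 2.72 in teratoma, 42.3 ± 11.5 in transplant, 14.0 ± 0.875 in embryo and 9.11 ± 0.916 in adult. Myf5 (chromosome 10 from 107482908 to 107486134) had 55.1 ± 15, 58.0 ± 8.72, 12.7 ± 2.5 and 42.0 ± 4.62, and Myod1, which commits cells to muscle (chromosome 7 from 46376474 to 46379099), 50.4 ± 12.6, 41.6 ± 13.3, 18.2 ± 6.35 and 403 ± 52.7. Myog, which drives terminal differentiation (chromosome 1 from 134289989 to 134292548), was at 29.7 ± 10, 40.7 ± 7.27, 20.9 ± 11.6 and 3.36 ± 1.21. Nfix, a transcription factor of fetal muscle (chromosome 8 from 84699876 to 84800344), was at 61.3 ± 1.48, 90.5 ± 9.64, 29.1 ± 4.34 and 35.8 ± 3.91. Pax3, the related early factor, stayed low at 0.511 ± 0.274, 0.169 ± 0.118, 1.71 ± 0.956 and 0.652 ± 0.386.

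**Figure D2:**
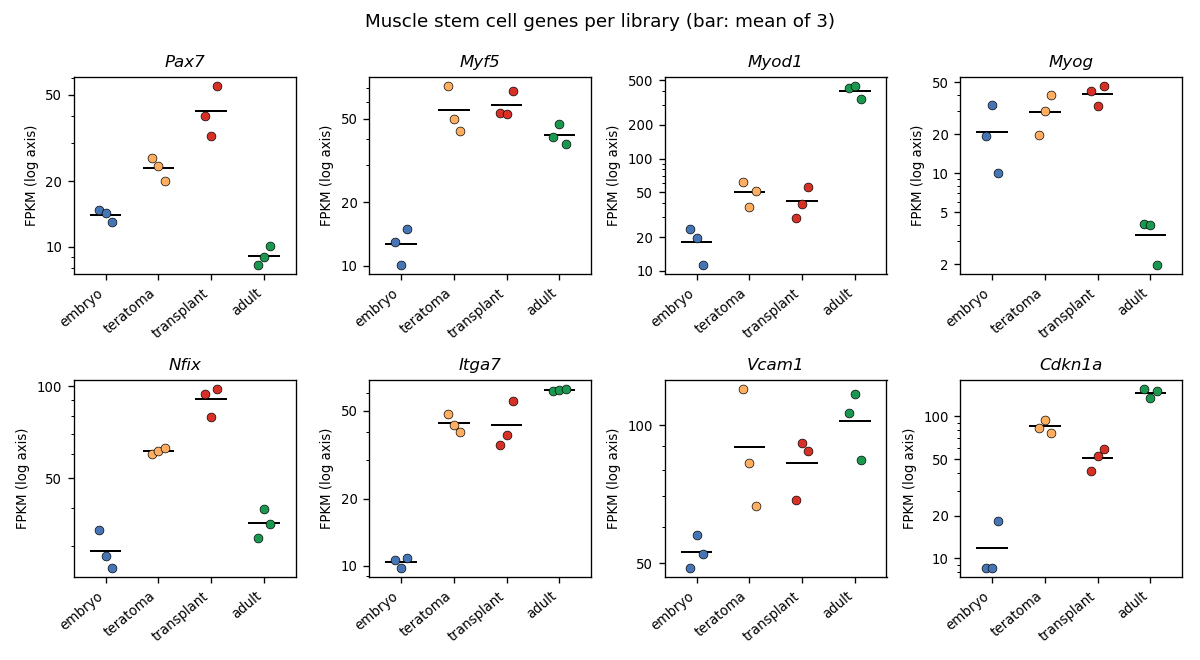
FPKM (log axis) of 8 genes of muscle progenitors in the 4 groups, with 1 point per library and a bar at the mean of 3. Myod1 is highest in adult, Myog is lowest there, and Pax7 is highest in transplant.

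Adult cells were first set against embryonic ones, the 2 native groups. The embryo cells came from whole embryos and the adult cells from hindlimbs. Stage and body site therefore cannot be told apart in this comparison, Hox genes included. Myod1 rose from 18.2 ± 6.35 to 403 ± 52.7 (log2 change 4.45, adjusted p = 2.32e-07) and Myf5 from 12.7 ± 2.5 to 42.0 ± 4.62 (log2 change 1.67, adjusted p = 3.3e-05), while Myog fell from 20.9 ± 11.6 to 3.36 ± 1.21 (log2 change -2.23, adjusted p = 0.000406). Itga7 and Vcam1 were higher in adult by 2.47 and 0.93 (adjusted p at most 0.00283). Among the largest increases were Asb5 (0, 0.142 and 0 in the embryo libraries, 652 ± 24.8 in adult), the neuropeptide gene Gal (0.308, 0 and 0.171 against 455 ± 37.7), Fam132b, which encodes erythroferrone (0.403, 0 and 0.0618 against 377 ± 23.6), and the metallothioneins Mt2 and Mt1 (log2 changes 8.02 and 7.04). Among the largest decreases were H19, a maternally expressed noncoding RNA (1466 ± 168 to 6.37 ± 0.186), Dlk1, an imprinted Notch-ligand-like protein (285 ± 40.7 to 1.09 ± 0.821), and the angiotensin receptor gene Agtr2, at 130.5 ± 19.8 in embryo and listed at 0 in all 3 adult libraries.

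Genes that mark quiescent satellite cells were mostly higher in adult, and genes of the cell cycle were lower. Of the 32 quiescence genes tested, 21 were higher and 6 lower (21 and 7 adjusted over the list alone), with a median log2 change of 1.08, camera adjusted p = 9.26e-08 and adjusted p = 0.0649 with an estimated correlation. Chrdl2, Fgl2 and the syndecan Sdc4 rose by 6.22, 5.59 and 5.17. All 29 S phase genes and all 32 G2 and M phase genes fell, also adjusted over the list alone, with medians of -3.09 and -3.75 (camera adjusted p = 8.66e-11, adjusted p = 0.0649 with an estimated correlation for the first, and camera adjusted p = 1.31e-14, adjusted p = 0.0649 with an estimated correlation for the other). Mcm6, Mcm2, Birc5, Cdk1 and Top2a fell by 4.91, 4.65, 5.24, 5.03 and 4.86 (adjusted p at most 1.19e-07). Replication histone genes, whose near-identical copies make single values uncertain, followed, with 0 higher and 54 lower of 55 (the same adjusted over the list alone) and a median of -4.26 (camera adjusted p = 8.66e-13, adjusted p = 0.0577 with an estimated correlation). The cyclin-dependent kinase inhibitor gene Cdkn1a rose by 3.62, from 11.8 ± 5.73 to 148 ± 10.8, and Musk and Chrnb1 of the neuromuscular junction by 4.82 and 3.03 (adjusted p at most 3.68e-07). The list these 3 belong to, genes of commitment and fusion, had 8 higher and 6 lower of 26 (the same adjusted over the list alone) and a median of 0.14 (camera adjusted p = 0.0232, adjusted p = 0.292 with an estimated correlation). Its call was lost with median-ratio scaling or quantile normalization (adjusted p = 0.131 and 0.0618). It was also lost without embryo replicate 3 (median 0.06, adjusted p = 0.0832, range over the alternatives 0.0049 to 0.131).

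Imprinted, oncofetal, anterior Hox, matrix and respiratory genes were lower in adult cells. Among 28 imprinted genes, 1 passed as higher and 19 as lower (2 and 20 adjusted over the list alone), and the median log2 change was -2.13 (camera adjusted p = 1.77e-05, adjusted p = 0.107 with an estimated correlation). Mest and the amino acid transporter gene Slc38a4 fell by 5.34 and 5.01. The oncofetal RNA-binding genes Igf2bp1 and Igf2bp3 and the chromatin gene Hmga2 fell by 4.35, 4.14 and 3.91 (adjusted p at most 6.84e-06). The list of such oncofetal regulators had 0 higher and 7 lower of 9 (1 and 7 adjusted over the list alone, camera adjusted p = 0.035, adjusted p = 0.382 with an estimated correlation), a call lost with a pseudocount of 0.1, library quality weights or the stricter filter, and without embryo replicate 2 (adjusted p for this library 0.0736, range over the alternatives 0.0108 to 0.102). The list of 12 anterior Hox genes held 0 higher and 12 lower (the same counts adjusted over the list alone), at a median log2 change of -2.12 and camera adjusted p = 0.00256 (adjusted p = 0.177 with an estimated correlation). Hoxb3 went from 8.17 ± 5.21 to 0.0633, 0 and 0.114. Central Hox genes had 0 higher and 6 lower of 9 (the same adjusted over the list alone), posterior Hox genes 0 higher and 2 lower of 5 (the same adjusted over the list alone) and position factors of limb and head muscle 0 higher and 6 lower of 11 (the same adjusted over the list alone), and none of these 3 lists was called (camera adjusted p = 0.176, 0.894 and 0.456). Of the 24 genes of the fibrillar matrix tested, 1 was higher and 18 lower (1 and 19 adjusted over the list alone), with a median log2 change of -1.20, camera adjusted p = 0.000425 and adjusted p = 0.465 with an estimated correlation. Beside them, fibroblast markers had 5 higher and 10 lower of 19 (the same adjusted over the list alone) and a median of -0.94, and cartilage markers 1 higher and 9 lower of 15 (the same adjusted over the list alone) and a median of -1.50. Neither of these lists was called (camera adjusted p = 0.718 and 0.176). Fbn2 and Fn1, for fibrillin 2 and fibronectin, fell by 6.15 and 3.72. Tests passed for 1 higher and 72 lower of 84 nuclear genes of oxidative phosphorylation (1 and 73 adjusted over the list alone, median log2 change -1.52, camera adjusted p = 4.11e-10, adjusted p = 0.0577 with an estimated correlation). Ndufc2 and Ndufs7 fell by 3.64 and 3.17 (adjusted p at most 3.39e-05).

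Immune and immediate early genes were higher in adult cells. Of the 28 genes of MHC class I and the interferon response tested, 15 were higher and 2 lower (17 and 2 adjusted over the list alone), with a median log2 change of 0.95, camera adjusted p = 5.21e-07 and adjusted p = 0.0649 with an estimated correlation. H2-K1 rose from 1.52, 0 and 0.667 to 95.5 ± 9.24 and H2-D1 from 1.73 ± 1.49 to 79.1 ± 15. Among 26 immediate early genes, 13 passed as higher and 6 as lower (the same counts adjusted over the list alone), and the median log2 change was 0.44 (camera adjusted p = 0.000425, adjusted p = 0.395 with an estimated correlation). That call was lost with quantile normalization (adjusted p = 0.0618, range over the alternatives 0.000181 to 0.0618). Myc and Zfp36 rose by 3.71 and 2.40, while Klf2 fell by 2.66 (adjusted p at most 4.16e-05). Markers of other cell types moved as well. The embryonic globin gene Hbb-y was at 116, 465 and 1188 in the embryo libraries and listed at 0 in all 3 adult libraries. Erythroid markers were 0 higher and 6 lower of 7 (the same adjusted over the list alone, camera adjusted p = 0.0409, adjusted p = 0.389 with an estimated correlation). Neural markers had 0 higher and 6 lower of 7 (the same adjusted over the list alone, camera adjusted p = 0.0211, adjusted p = 0.113 with an estimated correlation). Tendon markers had 4 higher and 0 lower of 10 (3 and 0 adjusted over the list alone, camera adjusted p = 0.025, adjusted p = 0.292 with an estimated correlation). The tendon call was lost with median-ratio scaling, quantile normalization and the stricter filter, and the erythroid one with that filter, a pseudocount of 0.1, library quality weights and only the 2 groups in the fit. Leaving out 1 library also ended these 3 calls: the erythroid one without adult replicate 1, embryo replicate 2 or embryo replicate 3 (adjusted p = 0.0539, 0.0634 and 0.0887, range over the alternatives 0.0104 to 0.103), the neural one without embryo replicate 2 (adjusted p = 0.0931, range 0.00475 to 0.0931) and the tendon one without embryo replicate 3 (adjusted p = 0.0763 against 0.0525 under median-ratio scaling, range 0.0137 to 0.117).

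In adult against embryo, limma called 6699 of 12699 genes, 2007 higher and 4692 lower (29.96% higher). The median change of all tested genes was -0.42, and -0.04 under median-ratio scaling, where 3282 were higher and 3299 lower (49.9% higher). Pax7, at -0.58 (adjusted p = 0.0238), was not called under median-ratio scaling (-0.08, adjusted p = 0.766) or quantile normalization (-0.19, adjusted p = 0.468), or without adult replicate 1, adult replicate 2 or embryo replicate 1 (adjusted p = 0.0782, 0.0572 and 0.0624, range over the alternatives 0.0119 to 0.766). Nfix, at 0.29 (adjusted p = 0.116), was called under median-ratio scaling (0.82, adjusted p = 0.00197) and without embryo replicate 1 (adjusted p = 0.0469, range 0.00197 to 0.316). Pax3, at -0.68 (adjusted p = 0.0655), was called without adult replicate 1 or embryo replicate 3 (adjusted p = 0.0484 and 0.0445, range 0.0445 to 0.794). Pecam1 differed by 0.22 (adjusted p = 0.744), with changes from -0.35 to 0.90 over the alternatives (adjusted p from 0.0559 to 0.989).

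Teratoma cells were then compared with embryonic cells. Myf5 was higher in teratoma, at 55.1 ± 15 against 12.7 ± 2.5 (log2 change 2.02, adjusted p = 3.32e-05), as were Myod1 (log2 change 1.45, adjusted p = 0.00328), Nfix (log2 change 1.06, adjusted p = 0.00035) and Itga7 (log2 change 1.98, adjusted p = 1.07e-05). Myog stood at 29.7 ± 10 against 20.9 ± 11.6 and was not called (adjusted p = 0.297). The largest increases were in Ttr, the thyroid hormone carrier (170.1 ± 68.8 in teratoma, listed at 0 in all 3 embryo libraries), Reg3g, an antibacterial lectin of gut epithelium (129.6 ± 92.0 against 0, 0.252 and 0), the metallothioneins Mt1 and Mt2 and the insulin-like growth factor binding gene Igfbp7 (6.52, 6.31 and 5.62). The largest decreases were in Hbb-y, Hba-x and Hba-a2 of the globins (-7.03, -5.96 and -4.89, Hba-a2 being nearly identical to Hba-a1) and in the imprinted genes Grb10, a growth-restraining adaptor (chromosome 11 from 11930508 to 12038683, 202 ± 10.7 to 1.08 ± 0.266), and H19 (chromosome 7 from 142575529 to 142578143, 1466 ± 168 to 14.7 ± 0.423). Igf2, the neighbour of H19 (chromosome 7 from 142650766 to 142666816), was at 1685 ± 92.1 in teratoma and 1296 ± 134 in embryo.

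Genes of quiescence, differentiation and fibres were higher in the teratoma sort, which also held markers of other cell types, given below. Among 32 quiescence genes, 22 passed as higher and 2 as lower (23 and 2 adjusted over the list alone), and the median log2 change was 1.14 (camera adjusted p = 5.37e-09, adjusted p = 0.0418 with an estimated correlation). The caveolin gene Cav1 rose by 4.30, Fgl2 by 3.61 and Sdc4 by 3.05 (adjusted p at most 1.36e-05). The list of 26 genes of myogenic commitment and fusion held 16 higher and 0 lower (17 and 0 adjusted over the list alone), at a median log2 change of 1.09 and camera adjusted p = 3.88e-06 (adjusted p = 0.0418 with an estimated correlation). Cdkn1a went from 11.8 ± 5.73 to 85.1 ± 9.36. Fibre genes had 15 higher and 0 lower of 22 (17 and 0 adjusted over the list alone) and a median of 1.60 (camera adjusted p = 3.82e-09, adjusted p = 0.0558 with an estimated correlation). Skeletal actin Acta1 rose from 0.643 ± 0.388 to 40.2 ± 19.3 and the fast myosin light chain gene Mylpf from 1.23 ± 1.01 to 26.2 ± 10.1 (adjusted p at most 5.25e-05). Cell cycle genes were lower, the S phase list with 0 higher and 23 lower of 29 (0 and 24 adjusted over the list alone, camera adjusted p = 1.73e-11, adjusted p = 0.0418 with an estimated correlation). The G2 and M phase list had 0 higher and 29 lower of 32 (0 and 30 adjusted over the list alone, camera adjusted p = 9.87e-15, adjusted p = 0.0457 with an estimated correlation). Uhrf1 and Ube2c fell by 1.66 and 1.90 (adjusted p at most 0.00334). Replication histones had 0 higher and 13 lower of 55 (the same adjusted over the list alone, camera adjusted p = 2.59e-07, adjusted p = 0.0457 with an estimated correlation).

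Hox genes, which mark position along the body axis, were lower in teratoma cells, as were imprinted genes. Tests passed for 0 higher and 10 lower of 12 anterior Hox genes (0 and 12 adjusted over the list alone, median log2 change -1.72, camera adjusted p = 6.95e-07, adjusted p = 0.0418 with an estimated correlation). The list of 9 central Hox genes held 0 higher and 6 lower (the same counts adjusted over the list alone), at a median log2 change of -1.88 and camera adjusted p = 2.47e-05 (adjusted p = 0.0418 with an estimated correlation). Posterior Hox genes had 0 higher and 2 lower of 5 (the same adjusted over the list alone, camera adjusted p = 0.0256, adjusted p = 0.125 with an estimated correlation), a call lost without teratoma replicate 2 (adjusted p = 0.0518, range over the alternatives 0.00157 to 0.0518). Hoxc4 went from 6.94 ± 2.29 to 0.523 ± 0.322 and Hoxc8 from 4.65 ± 1.48 to 0.145 ± 0.0486 (adjusted p at most 0.000572). Of the 28 imprinted genes tested, 2 were higher and 13 lower (2 and 14 adjusted over the list alone), with a median log2 change of -0.55, camera adjusted p = 1.58e-05 and adjusted p = 0.076 with an estimated correlation. Mest and Plagl1 fell by 3.20 and 2.70. Class I and interferon genes were higher, 26 higher and 0 lower of 28 (the same adjusted over the list alone) with a median of 2.04 (camera adjusted p = 5.87e-17, adjusted p = 0.0225 with an estimated correlation). Isg15 went from 0, 0.191 and 0 in the embryo libraries to 21.6 ± 8.87, and H2-D1 from 1.73 ± 1.49 to 37.7 ± 5.43. Of the 26 immediate early genes tested, 21 were higher and 0 lower (23 and 0 adjusted over the list alone), with a median log2 change of 1.27, camera adjusted p = 1.56e-13 and adjusted p = 0.076 with an estimated correlation. Zfp36 rose by 2.63 (adjusted p at most 4.89e-05 for these genes).

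Markers of other cell types moved with these groups. The values are of whole sorts, so whether other cells contributed to the higher quiescence or class I genes cannot be told. Epithelial markers had 10 higher and 0 lower of 14 (the same adjusted over the list alone, camera adjusted p = 1.72e-06, adjusted p = 0.18 with an estimated correlation), with the keratins Krt8 at 45.8 ± 23 against 2.05 ± 1.38, Krt18 at 45.4 ± 23 against 1.98 ± 0.832 and Krt19 at 39.6 ± 19.7 against 0.387, 0 and 3.98. Leukocyte markers had 13 higher and 0 lower of 17 (16 and 0 adjusted over the list alone, camera adjusted p = 9.85e-07, adjusted p = 0.125 with an estimated correlation). The macrophage lysozyme gene Lyz2 was at 45.9 ± 27.7 in teratoma and 2.18 ± 2.53 in embryo, and the complement gene C1qa at 8.64 ± 3.06 and listed at 0 in all 3 embryo libraries. Endothelial markers had 5 higher and 1 lower of 15 (the same adjusted over the list alone, camera adjusted p = 0.013, adjusted p = 0.218 with an estimated correlation), a call lost without teratoma replicate 3 (adjusted p = 0.058, range over the alternatives 0.000494 to 0.058). Erythroid markers had 0 higher and 4 lower of 7 (the same adjusted over the list alone, camera adjusted p = 0.000867, adjusted p = 0.125 with an estimated correlation). Smooth muscle and pericyte markers had 8 higher and 1 lower of 13 (8 and 2 adjusted over the list alone, camera adjusted p = 0.00893, adjusted p = 0.0931 with an estimated correlation), a call lost with the stricter filter (adjusted p = 0.0584, range over the alternatives 0.00303 to 0.0584). Fibroblast markers had 6 higher and 6 lower of 19 (the same adjusted over the list alone) and were not called (camera adjusted p = 0.811).

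Across all genes, limma called 3308 of 12699 in teratoma against embryo, 1965 higher and 1343 lower, with a median change of 0.01. Without teratoma replicate 2 the count was 2123. Pax7, at 0.67 (adjusted p = 0.0225), was not called without embryo replicate 3, teratoma replicate 1 or teratoma replicate 2 (adjusted p = 0.0606, 0.0693 and 0.0711, range over the alternatives 0.0122 to 0.0711). Vcam1, at 0.71 (adjusted p = 0.0274), was not called with only the 2 groups in the fit or without embryo replicate 1, embryo replicate 3, teratoma replicate 1 or teratoma replicate 2 (adjusted p = 0.0696, 0.0752, 0.061, 0.0944 and 0.0617, range 0.0123 to 0.0944). Pecam1, at 1.12 (adjusted p = 0.125), was called with library quality weights or without embryo replicate 2 (adjusted p = 0.0214 and 0.00465, range 0.00465 to 0.399), at a change of 1.81 without that library. Pax3, at -0.80 (adjusted p = 0.0616), was called with quantile normalization or without embryo replicate 3 (adjusted p = 0.0333 and 0.0487, range 0.0333 to 0.207).

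Transplanted cells were next compared with sorted teratoma cells, the kind that had been transplanted. Pax7 was higher after transplantation, 42.3 ± 11.5 against 23.1 ± 2.72 (log2 change 0.82, adjusted p = 0.0103). Myf5, Myod1, Myog, Itga7 and Vcam1 differed by 0.09, -0.28, 0.48, -0.05 and -0.09, and none of these was called (adjusted p at least 0.405). The largest increases were in Tnmd, a membrane glycoprotein of tendon (58.9 ± 26.5 against 2.96 ± 2.81), Thbs4 of the thrombospondins (366 ± 119 against 30.6 ± 9.03), the cell cycle inhibitor gene Cdkn2a (28.3 ± 6.61 against 0, 3.46 and 2.08), and the matrix genes Fbln7 and Epyc (3.57 and 3.42, adjusted p at most 0.000275 for the 5 genes). Ttr, Reg3g and Cldn4 were listed at 0 in all 3 transplant libraries, against 170.1 ± 68.8, 129.6 ± 92.0 and 55.4 ± 35.8 in teratoma. The keratin Krt8 fell from 45.8 ± 23 to 0, 0.0963 and 0.147 in the single transplant libraries, and Krt18 from 45.4 ± 23 to 0.0583, 0 and 0.

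Quiescence genes were higher and cell cycle genes lower after transplantation, between sorts that also differed in markers of other cell types. The list of 32 quiescence genes held 14 higher and 1 lower (14 and 2 adjusted over the list alone), at a median log2 change of 0.43 and camera adjusted p = 1.87e-08 (adjusted p = 0.0337 with an estimated correlation). Asb5 and Chrdl2 rose by 2.73 and 2.45. Cdkn1c, an imprinted cyclin-dependent kinase inhibitor gene also on this list, went the other way, from 275 ± 37.1 to 26.7 ± 6.69 (log2 change -3.34, adjusted p = 3.06e-05). S phase genes had 0 higher and 26 lower of 29 (0 and 29 adjusted over the list alone, camera adjusted p = 2.58e-14, adjusted p = 0.0337 with an estimated correlation). G2 and M phase genes had 0 higher and 32 lower of 32 (the same adjusted over the list alone, camera adjusted p = 2.61e-18, adjusted p = 0.0337 with an estimated correlation). Mcm5 fell by 3.08, Top2a by 2.96, Cdk1 by 2.91 and the proliferation marker Mki67 by 2.70 (adjusted p at most 0.000122). Tests passed for 0 higher and 41 lower of 55 replication histone genes (0 and 49 adjusted over the list alone, median log2 change -2.47, camera adjusted p = 4.64e-15, adjusted p = 0.0181 with an estimated correlation). Among imprinted genes, counts were 0 higher and 18 lower of 28 (0 and 21 adjusted over the list alone, camera adjusted p = 8.01e-09, adjusted p = 0.0337 with an estimated correlation), and Dlk1, Slc38a4 and H19 fell by 4.43, 3.96 and 2.85. Oncofetal regulators had 0 higher and 6 lower of 9 (0 and 7 adjusted over the list alone, camera adjusted p = 0.000933, adjusted p = 0.146 with an estimated correlation), with Igf2bp1 and Hmga1 lower by 2.17 and 2.22 (adjusted p at most 0.00408 for these 5 genes).

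Some heat shock genes were higher and glycolytic genes mostly lower in transplant cells. Of the 18 heat shock and unfolded protein genes tested, 7 were higher and 0 lower (7 and 2 adjusted over the list alone), with a median log2 change of 0.29, camera adjusted p = 4.8e-07 and adjusted p = 0.0852 with an estimated correlation. Hspa1a and Hspa1b, nearly identical copies whose values are uncertain apart, rose by 2.63 and 2.66, and Hspb1 and Dnajb1 by 2.16 and 1.75. The list of 26 immediate early genes held 6 higher and 2 lower (7 and 2 adjusted over the list alone), at a median log2 change of 0.37 and camera adjusted p = 5.66e-06 (adjusted p = 0.201 with an estimated correlation). Their median was 0.20 without teratoma replicate 1. Among 20 genes of glycolysis, 0 passed as higher and 16 as lower (the same counts adjusted over the list alone), and the median log2 change was -1.07 (camera adjusted p = 3.51e-06, adjusted p = 0.109 with an estimated correlation). The glucose transporter gene Slc2a1 and Pgk1 fell by 1.64 and 1.58 (adjusted p at most 0.000728 for the 6 genes). Ribosomal protein genes had 0 higher and 48 lower of 92 (1 and 59 adjusted over the list alone) and a median of -0.56 (camera adjusted p = 5.28e-08, adjusted p = 0.236 with an estimated correlation), against -0.28 for all genes. Under median-ratio scaling 1 of them was higher and 7 were lower, and of the glycolysis genes 9 were lower. Genes of commitment and fusion had 4 higher and 2 lower of 26 (4 and 3 adjusted over the list alone), with a median of -0.20, a mean of 0.08 and a camera direction that was up (camera adjusted p = 0.0321, adjusted p = 0.201 with an estimated correlation). Under median-ratio scaling the median turned to 0.03 (adjusted p = 0.0517). The call was also lost with a pseudocount of 0.1, quantile normalization, the stricter filter at a mean of 5 FPKM or only the 2 groups in the fit, and without teratoma replicate 1, teratoma replicate 2 or transplant replicate 3 (adjusted p for these libraries 0.075, 0.0776 and 0.119, range over the alternatives 0.00908 to 0.261). Over the alternatives the median ran from -0.28 to 0.16. Anterior and central Hox genes had medians of -0.01 and 0.01 and were not called (camera adjusted p = 0.179 and 0.0935). Posterior Hox genes had 2 higher and 0 lower of 5 (the same adjusted over the list alone) and a median of 0.61 (camera adjusted p = 0.047, adjusted p = 0.17 with an estimated correlation). This call was lost with median-ratio scaling or quantile normalization (adjusted p = 0.155 and 0.0901) and without adult replicate 3, teratoma replicate 2, transplant replicate 1 or transplant replicate 3 (adjusted p = 0.0512, 0.139, 0.0619 and 0.0885, range over the alternatives 0.0155 to 0.155). The median was 0.30 without teratoma replicate 2 and 0.14 without transplant replicate 3.

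Fibroblast and tendon markers rose beside the quiescence genes, while epithelial, smooth muscle, endothelial and cartilage markers fell. Among 19 fibro-adipogenic and fibroblast markers, 11 passed as higher and 1 as lower (15 and 1 adjusted over the list alone), and the median log2 change was 0.78 (camera adjusted p = 2.58e-14, adjusted p = 0.082 with an estimated correlation). Gsn went from 93.5 ± 15 to 798 ± 53.5, Smoc2 from 16.4 ± 3.40 to 109 ± 25.9, Mfap5 from 18.5 ± 10.5 to 94.8 ± 12.7 and Pi16 from 16.1 ± 8.52 to 87.4 ± 28.4 (adjusted p at most 0.00388). Of the 10 tendon markers tested, 6 were higher and 0 lower (7 and 0 adjusted over the list alone), with a median log2 change of 2.48, camera adjusted p = 1.19e-10 and adjusted p = 0.0181 with an estimated correlation. Epithelial markers had 0 higher and 13 lower of 14 (the same adjusted over the list alone, camera adjusted p = 3.12e-08, adjusted p = 0.17 with an estimated correlation). Smooth muscle markers had 0 higher and 9 lower of 13 (the same adjusted over the list alone, camera adjusted p = 0.00152, adjusted p = 0.0685 with an estimated correlation), a call lost with the stricter filter (adjusted p = 0.103, range over the alternatives 0.000174 to 0.103). Endothelial markers had 0 higher and 9 lower of 15 (0 and 10 adjusted over the list alone, camera adjusted p = 0.00468, adjusted p = 0.201 with an estimated correlation), with Cdh5 at 18.7 ± 2.00 and 2.87 ± 0.0240. Cartilage markers had 0 higher and 8 lower of 15 (0 and 11 adjusted over the list alone, camera adjusted p = 0.000344, adjusted p = 0.131 with an estimated correlation), and the cartilage collagen gene Col2a1 went from 27.6 ± 12.4 to 0.338 ± 0.175 (adjusted p at most 0.000122). Leukocyte markers had 0 higher and 4 lower of 17 (the same adjusted over the list alone) and were not called (camera adjusted p = 0.172). Neural markers were called (camera adjusted p = 0.0484), with medians from -2.06 to -0.31 over the alternatives. That call was lost under 9 of 18 alternatives, the replicate block among them (adjusted p = 0.0572, range 0.00843 to 0.113), and with an estimated correlation.

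In transplant against teratoma, limma called 2874 of 12699 genes, 531 higher and 2343 lower (18.5% higher). The median change of all tested genes was -0.28, and -0.03 under median-ratio scaling, where 921 were higher and 1209 lower (43.2% higher). Leaving out teratoma replicate 1 gave 1524 and leaving out transplant replicate 1 gave 1803. Nfix, at 0.55 (adjusted p = 0.0215), was not called without teratoma replicate 1, teratoma replicate 2, transplant replicate 1 or transplant replicate 3 (adjusted p = 0.0652, 0.0578, 0.0712 and 0.0735, range over the alternatives 0.00575 to 0.0735). Pecam1, at -1.43 (adjusted p = 0.0613), was called with library quality weights, with only the 2 groups in the fit, and without embryo replicate 1 or embryo replicate 2 (adjusted p = 0.0291, 0.0127, 0.0271 and 0.00871, range 0.00871 to 0.197), and Pax3 differed by -0.36 (adjusted p = 0.409).

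Transplant cells were also compared with adult satellite cells, the native cells of the muscle they were taken from. Pax7 was higher in transplant (log2 change 2.07, adjusted p = 1.23e-05), as were Myog (log2 change 3.29, adjusted p = 4.68e-05) and Nfix (log2 change 1.31, adjusted p = 3.89e-05). Myod1 was lower, at 41.6 ± 13.3 against 403 ± 52.7 (log2 change -3.28, adjusted p = 9.08e-06). Among the largest increases were Ptn, the growth factor pleiotrophin (162 ± 50.7 against 3.81 ± 1.37), Ifi27l2a (35.2 ± 13) and Cdkn2a (28.3 ± 6.61), the last 2 listed at 0 in all 3 adult libraries. Idh3b and Spcs1, at 26.6 ± 1.23 and 26.1 ± 4.98 in transplant, were also listed at 0 in all 3 adult libraries. Spcs1 was listed at 0 in teratoma replicate 1 and embryo replicate 2 too. The largest decreases were in Fam132b, Procr, the protein C receptor gene, Gal, Grb10 and Hprt (-6.20, -5.51, -5.16, -4.93 and -4.74, adjusted p at most 1.32e-05). Procr was at 2.38 ± 1.38 against 153 ± 56.8.

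Genes of the fibrillar matrix were higher in transplant cells, beside fibroblast and tendon markers. Tests passed for 24 higher and 0 lower of 24 genes of the fibrillar matrix (the same counts adjusted over the list alone, median log2 change 2.41, camera adjusted p = 2.52e-13, adjusted p = 0.423 with an estimated correlation). Fn1 was at 466 ± 135 against 17.7 ± 2.04, the matricellular gene Postn at 313 ± 121 against 16.9 ± 1.29 and Col12a1 at 68.3 ± 20 against 3.77 ± 1.03. Basement membrane genes had 14 higher and 1 lower of 22 (15 and 1 adjusted over the list alone, camera adjusted p = 0.000652, adjusted p = 0.423 with an estimated correlation). The list of 19 fibro-adipogenic and fibroblast markers held 15 higher and 0 lower (the same counts adjusted over the list alone), at a median log2 change of 2.11 and camera adjusted p = 2.88e-06 (adjusted p = 0.423 with an estimated correlation). Mfap5, Col1a2 and Cd248 were higher by 4.24, 2.90 and 2.86. Among 10 tendon markers, 9 passed as higher and 0 as lower (the same counts adjusted over the list alone), and the median log2 change was 1.90 (camera adjusted p = 0.000581, adjusted p = 0.423 with an estimated correlation). Thbs4 and Tnmd were higher by 3.86 and 3.26 (adjusted p at most 0.000348 for the 8 genes). Leukocyte markers had 8 higher and 0 lower of 17 (8 and 1 adjusted over the list alone) and were not called (camera adjusted p = 0.0606), and epithelial markers had a median of 0.00 (camera adjusted p = 0.827).

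Contractile, interferon and respiratory genes were also higher in transplant cells. Of the 22 adult fibre genes tested, 14 were higher and 0 lower (15 and 0 adjusted over the list alone), with a median log2 change of 1.17, camera adjusted p = 0.0013 and adjusted p = 0.423 with an estimated correlation. The stricter filter ended this call (adjusted p = 0.118, range over the alternatives 5.41e-05 to 0.118). Mylpf and Acta1 were higher by 3.65 and 2.83. Developmental contractile genes had 7 higher and 0 lower of 11 (9 and 0 adjusted over the list alone, camera adjusted p = 0.0163, adjusted p = 0.423 with an estimated correlation), with cardiac actin Actc1 at 15.6 ± 4.99 against 0.132, 1.01 and 0. Interferon and class I genes had 18 higher and 3 lower of 28 (the same adjusted over the list alone, camera adjusted p = 0.00289, adjusted p = 0.423 with an estimated correlation), and Usp18, Isg15 and Irf7 were higher by 3.30, 3.28 and 2.96. Immediate early genes had 17 higher and 2 lower of 26 (17 and 3 adjusted over the list alone, camera adjusted p = 0.000768, adjusted p = 0.647 with an estimated correlation), with Fos and Cyr61 higher by 2.91 and 2.57. Genes of oxidative phosphorylation had 43 higher and 2 lower of 84 (the same adjusted over the list alone, camera adjusted p = 0.000248, adjusted p = 0.423 with an estimated correlation), with Ndufs7 higher by 2.95 (adjusted p at most 0.000445 for the genes named). Quiescence genes went both ways, 11 higher and 7 lower of 32 (the same adjusted over the list alone, camera adjusted p = 0.827). Asb5 was lower by 3.26, and Sdc3 was higher by 3.45, as was the Notch target Hes1 by 3.14. Imprinted genes had 9 higher and 9 lower of 28 (the same adjusted over the list alone) and were not called (camera adjusted p = 0.438), and Igf2 was at 865 ± 213 against 45.4 ± 7.02. Cell cycle lists were not called: S phase genes had 5 higher and 5 lower of 29 (4 and 4 adjusted over the list alone) and G2 and M phase genes 5 higher and 1 lower of 32 (0 and 0 adjusted over the list alone, camera adjusted p = 0.671 and 0.404).

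In transplant against adult, limma called 5612 of 12699 genes, 3462 higher and 2150 lower (61.7% higher). The median change of all tested genes was 0.23, and 0.09 under median-ratio scaling, where 3047 were higher and 2831 lower (51.8% higher). Itga7, at -0.54 (adjusted p = 0.021), was not called with quantile normalization (adjusted p = 0.0891) or without adult replicate 1, 2 or 3 or transplant replicate 1 or 2 (adjusted p = 0.052, 0.0524, 0.0547, 0.0942 and 0.0699, range over the alternatives 0.00245 to 0.0942). Myf5 at 0.45 and Vcam1 at -0.30 were not called (adjusted p = 0.0956 and 0.274). With quantile normalization or only the 2 groups in the fit Myf5 was called (adjusted p = 0.0238 and 0.0417, range 0.0238 to 0.286), and with median-ratio scaling Vcam1 was called lower (adjusted p = 0.0399, range 0.0399 to 0.787). Pax3 and Pecam1 differed by -0.48 and -0.52 (adjusted p = 0.204 and 0.43).

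The remaining 2 comparisons cross the stages. In teratoma against adult, Ttr and Reg3g (listed at 0 in all 3 adult libraries) and Dlk1 (149 ± 14.8 against 1.09 ± 0.821) stood out as higher, and Fam132b, Asb5 and the complement gene C7 as lower (-7.12, -5.99 and -5.11). Myog and Pax7 were higher by 2.81 and 1.25 and Myod1 lower by 3.00 (adjusted p at most 0.000315). Myf5, Vcam1, Pax3 and Pecam1 were not called (0.36, -0.21, -0.12 and 0.91). G2 and M phase genes had 32 higher and 0 lower of 32 (the same adjusted over the list alone, camera adjusted p = 1.89e-11, adjusted p = 0.203 with an estimated correlation). Epithelial markers had 13 higher and 0 lower of 14 (the same adjusted over the list alone, camera adjusted p = 5.29e-05, adjusted p = 0.347 with an estimated correlation). Leukocyte markers had 14 higher and 0 lower of 17 (the same adjusted over the list alone, camera adjusted p = 0.00357, adjusted p = 0.4 with an estimated correlation). Cartilage markers had 11 higher and 0 lower of 15 (12 and 0 adjusted over the list alone, camera adjusted p = 0.00768, adjusted p = 0.282 with an estimated correlation). Smooth muscle markers had 9 higher and 1 lower of 13 (11 and 1 adjusted over the list alone, camera adjusted p = 0.0319, adjusted p = 0.247 with an estimated correlation). This call was lost with a pseudocount of 0.1 or the stricter filter (adjusted p = 0.0503 and 0.101) and without embryo replicate 2 (adjusted p = 0.0592, range over the alternatives 0.00338 to 0.101). In all, 5763 genes were called, 4628 higher and 1135 lower (80.3% higher), against 2929 and 2586 (53.1%) under median-ratio scaling, which moved the median of all genes from 0.50 to 0.13. Under that scaling Nfix, at 0.77 (adjusted p = 0.00147), was not called (adjusted p = 0.286, range over the alternatives 0.000737 to 0.286), and Vcam1 was called lower (adjusted p = 0.00737, range 0.00737 to 0.937). Pax3 was called lower with quantile normalization (adjusted p = 0.0444, range 0.0444 to 0.955). Itga7, at -0.49 (adjusted p = 0.0321), was not called without adult replicate 1, 2 or 3 or teratoma replicate 2 or 3 (adjusted p = 0.0715, 0.0719, 0.0759, 0.0786 and 0.0987, range 0.000437 to 0.0987). Pecam1 was called with only the 2 groups in the fit or without embryo replicate 2 (adjusted p = 0.0415 and 0.0365, range 0.0365 to 0.715).

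In transplant against embryo, the highest increases were in Mt1, Mt2 and the cartilage matrix gene Cilp (8.18, 7.68 and 7.29). The strongest decreases were in H19 (1466 ± 168 to 1.17 ± 0.238) and the globins Hbb-y and Hba-x, the latter listed at 0 in all 3 transplant libraries. Pax7, Myf5, Nfix and Itga7 were higher by 1.49, 2.12, 1.61 and 1.93, Myod1 by 1.17 and Pax3 lower by 1.16 (adjusted p at most 0.00671). Of the 32 quiescence genes tested, 28 were higher and 1 lower (the same counts adjusted over the list alone), with a median log2 change of 1.46, camera adjusted p = 4.72e-15 and adjusted p = 0.0115 with an estimated correlation. Among markers of other cell types, fibro-adipogenic ones had 12 higher and 4 lower of 19 (the same adjusted over the list alone, camera adjusted p = 5.26e-05, adjusted p = 0.262 with an estimated correlation). Tendon markers had 8 higher and 0 lower of 10 (the same adjusted over the list alone, camera adjusted p = 6.87e-08, adjusted p = 0.0181 with an estimated correlation). Leukocyte markers had 7 higher and 0 lower of 17 (the same adjusted over the list alone, camera adjusted p = 0.00091, adjusted p = 0.279 with an estimated correlation). Erythroid markers had 0 higher and 6 lower of 7 (the same adjusted over the list alone, camera adjusted p = 0.0017, adjusted p = 0.126 with an estimated correlation). Neural markers had 0 higher and 7 lower of 7 (the same adjusted over the list alone, camera adjusted p = 0.00574, adjusted p = 0.0561 with an estimated correlation), a call lost without embryo replicate 2 (adjusted p = 0.0677, range over the alternatives 0.00125 to 0.0677). A total of 5394 genes was called, 1889 higher and 3505 lower (35.0% higher), against 2546 and 2420 (51.3%) under median-ratio scaling, which moved the median of all genes from -0.24 to 0.00. Myog, at 1.06 (adjusted p = 0.0416), was not called with no filter, a pseudocount of 0.1, the replicate number as a block or only the 2 groups in the fit, or without embryo replicate 1, embryo replicate 3, teratoma replicate 2, transplant replicate 1 or transplant replicate 3 (for these libraries adjusted p = 0.0758, 0.166, 0.0528, 0.0995 and 0.114, range over the alternatives 0.00695 to 0.166), and its change was 0.64 without embryo replicate 3. Vcam1, at 0.63 (adjusted p = 0.0315), was not called without embryo replicate 1, embryo replicate 3, transplant replicate 2 or transplant replicate 3 (adjusted p = 0.0849, 0.0687, 0.1 and 0.0883, range 0.00179 to 0.1). Pecam1 differed by -0.30 (adjusted p = 0.662), with changes from -0.87 to 0.38 over the alternatives (adjusted p from 0.142 to 0.909).

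**Figure D3:**
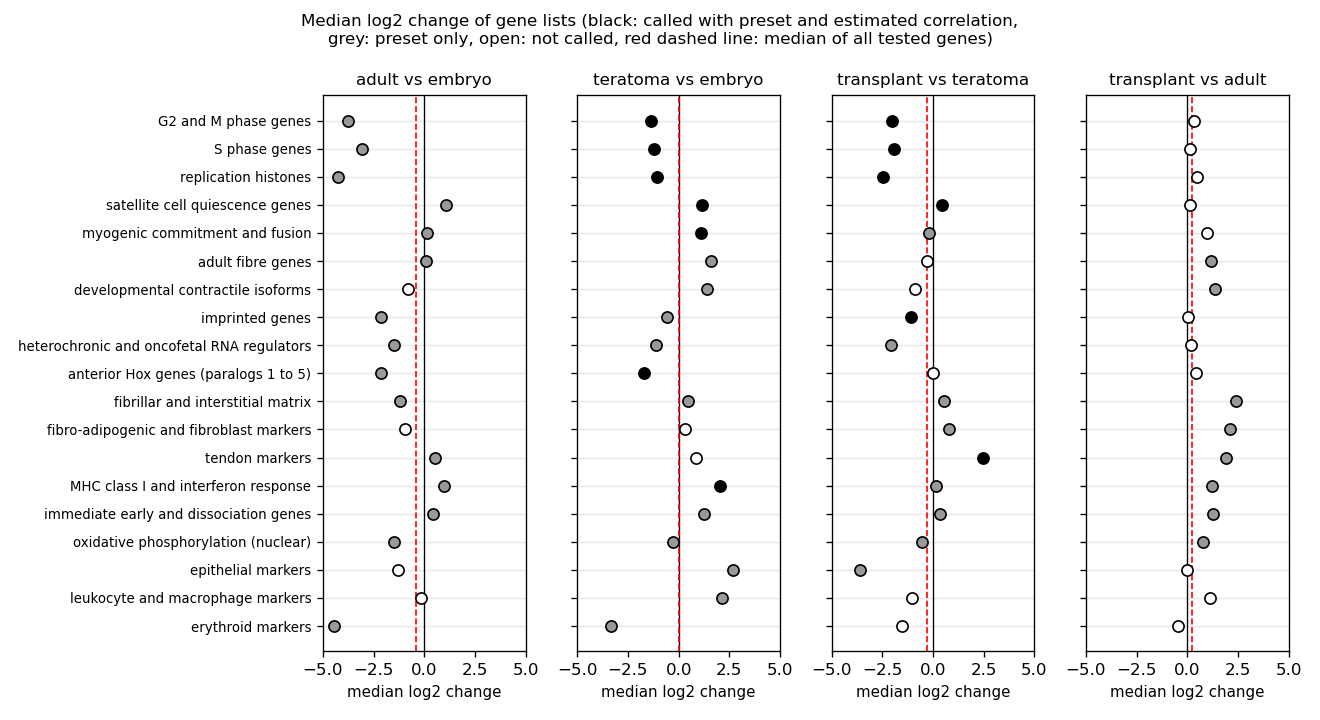
Median log2 change (horizontal axis) of 19 gene lists in 4 comparisons, with black points for lists called by camera with the preset and the estimated correlation, grey points for the preset correlation only and open points for lists not called. The red dashed line is the median of all tested genes, from -0.42 in adult against embryo to 0.23 in transplant against adult.

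The list calls that held with an estimated correlation were 8 in teratoma against embryo (quiescence, commitment, S phase, G2 and M phase, anterior and central Hox genes, class I and interferon, and replication histones) and 6 in transplant against teratoma (quiescence, S phase, G2 and M phase, imprinted genes, replication histones and tendon markers). In transplant against embryo there were 8 (quiescence, commitment, S phase, G2 and M phase, imprinted genes, class I and interferon, replication histones and tendon markers). None held in the other 3 comparisons.

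The stem-cell-derived groups were placed on an axis from embryo (0) to adult (1) over all tested genes, with the axis and its ends taken from different libraries. Teratoma cells lay at 0.352 ± 0.0122 and transplant cells at 0.556 ± 0.0339, with embryo at -0.00105 ± 0.0486 and adult at 1.00 ± 0.0498. Transplant exceeded teratoma by 0.205, with each transplant library above each teratoma library. The 2-sided exact permutation test gave p = 0.1, the smallest that 20 arrangements of 3 against 3 libraries allow. The ends of the axis differ in body site (whole embryo and hindlimb) as well as in stage, so a position does not measure stage alone. The axis also covers only part of the profile. On the second principal component (20.8% of the variance), transplant libraries scored 48.9 to 62.0 and teratoma libraries 13.3 to 32.7. Embryo libraries scored -55.0 to -29.9 there and adult libraries -45.3 to -38.7, so both stem-cell-derived groups also lay apart from both native groups. Genes called in both transplant against teratoma and adult against embryo changed in the same direction in 1303 cases and in opposite directions in 501 (72.2% the same). Independent lists would give 83.9 shared higher genes against 202 observed, 866 shared lower against 1101, and 370.3 and 196 in opposite directions against 382 and 119. Across genes, which are not independent replicates, the log2 changes had Pearson's r = 0.252 and Spearman's rho = 0.128. The comparisons of teratoma with embryo and of transplant with adult shared 824 calls in the same direction and 825 in opposite directions (r = -0.00661). Both higher were 641 genes (536 for independent lists) and both lower 183 (227). Higher in teratoma and lower in transplant were 439 (333), and lower in teratoma and higher in transplant 386 (366). The count shared in the same direction was 521 without teratoma replicate 2. Neither pair of comparisons has a library in common. Both comparisons of a pair do share the same estimate of each gene's spread, so the counts for independent lists are only a rough reference.

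**Figure D4:**
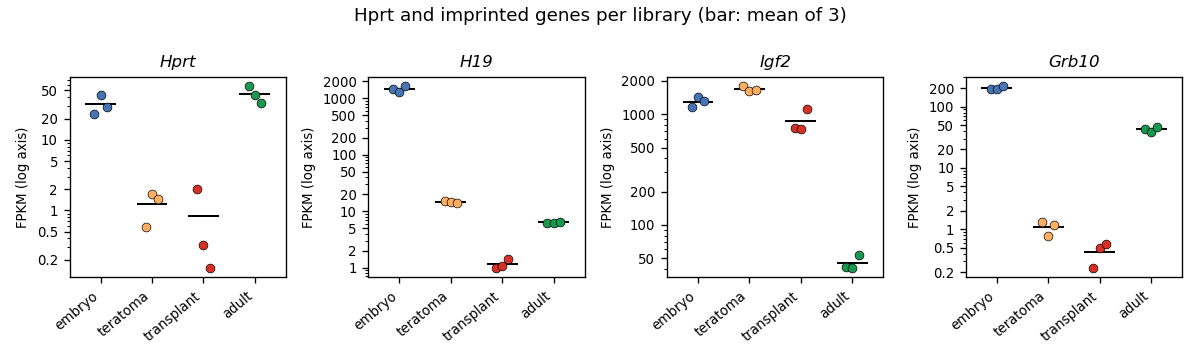
FPKM (log axis) of Hprt, H19, Igf2 and Grb10 in the 4 groups, with 1 point per library and a bar at the mean of 3. Hprt and Grb10 are lower in all 6 stem-cell-derived libraries than in any embryo or adult library.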

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

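The tests in this part were chosen after the results were seen, except the one on the neighbours of Hprt. Both stem-cell-derived groups were compared with a native stage, and limma tested whether teratoma against embryo differed from transplant against adult. This difference passed for 4943 of 12699 genes. By construction it equals the change from embryo to adult less the change from teratoma to transplant. For Itga7, Myod1, Myf5 and Vcam1 it was 2.52 (adjusted p = 1.81e-05), 4.73 (adjusted p = 1.01e-05), 1.57 (adjusted p = 0.00144) and 1.01 (adjusted p = 0.0189). The transplant against teratoma changes of these 4 genes were -0.05, -0.28, 0.09 and -0.09, none of them called. Those of adult against embryo were 2.47, 4.45, 1.67 and 0.93. The values for these genes therefore restate most of the difference between the native stages and do not test teratoma against transplant. For Pax7 and Myog it was -1.40 (adjusted p = 0.00193) and -2.70 (adjusted p = 0.00229), with adult against embryo at -0.58 and -2.23 and transplant against teratoma at 0.82 and 0.48, the last of which was not called. All 6 kept their direction and their call under median-ratio scaling (adjusted p at most 0.00598).

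Hprt was far below the native groups in all 6 stem-cell-derived libraries. A failed estimate is argued against by values above 0 in all 6, the highest 8.65% of the lowest embryo or adult one, and scaling by a change of -3.76 (SE 0.393) under median-ratio scaling, the smaller of its 2 changes. A loss shared with its surroundings in both groups is argued against by the 7 tested genes within 1 Mb. Their median change was 0.68 (SE of the mean over genes 0.348) in transplant against adult. In teratoma against embryo their median was -1.02, so a shared loss stays open for teratoma taken alone. A change limited to Hprt in the injected stem cells may account for the pattern: Hprt-deficient embryonic stem cell lines of the labelled strain are known, but the labels name no line. This stays a hypothesis.

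Fibroblast and tendon genes were higher in transplant than in teratoma cells. Host cells as the main source are argued against by Hprt, provided that host cells express it. Its highest value in a transplant library was 6.18% of the lowest adult one. The epithelial markers, whose median fell by 3.597 (SE of the mean over genes 0.459), cannot decide on a lower share of muscle cells. The source tissue changed from a mixed-tissue tumour to muscle, so these markers could fall whatever that share was. More fibroblasts of donor origin in the sort could not be told apart from a change within the muscle cells: the 19 fibro-adipogenic markers had a median of 0.78, but 8 were not called higher. Of these markers, 18 reached 1 FPKM in the adult sort too and 3 stand in another list, as does 1 of 10 tendon markers. The most abundant in transplant were Col1a1, Col1a2 and Col3a1 (2320.0 ± 632 against 1400.0 ± 475 in teratoma, 1880.0 ± 406 against 1158 ± 291 in teratoma, 1516 ± 280.2 against 1006 ± 149 in teratoma). A gate on α7-integrin should remove fibroblasts that lack it. The same gate left epithelial and macrophage markers in the teratoma sort, so it cannot decide on fibroblasts.

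H19 and Grb10, both imprinted, were far lower in teratoma and transplant cells than in embryo. Failed estimates are argued against by the values, none at 0, the highest 1.16% of the lowest embryo one. Maturation is argued against for Grb10, whose lowest adult value was 29.8 times the highest teratoma one. It is also argued against for H19 in transplant, whose highest value was 23.2% of the lowest adult one, past the adult end. For H19 in teratoma, whose lowest value was 2.16 times the highest adult one, the level of H19 alone leaves maturation open. Igf2, the neighbour of H19, was also far lower in adult than in embryo. In teratoma against embryo, however, Igf2 changed by 0.38, beside -6.54 for H19. This argues against a maturation that lowers both genes together. A general loss from maternal alleles is argued against by the other 8 maternally expressed genes tested. Their median change was -0.55 (SE of the mean over genes 0.255) in teratoma against embryo, beside -0.29 over 17 paternally expressed ones. A change at these 2 genes in the stem cells may be the source, a hypothesis that stays open without methylation data, which were not used here.

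The libraries of each comparison can be arranged in 10 ways as 3 against 3, too few for a share under 0.05. The number with a count as large as the real one was 1, the real one, in each comparison. Every other arrangement mixes the 2 groups, which places their difference in the spread and keeps the count low. The other counts therefore do not measure chance. The counts were 6699 in adult against embryo (highest other 2), 3308 in teratoma against embryo (highest other 2), 5763 in teratoma against adult (highest other 3), 2874 in transplant against teratoma (highest other 4), 5612 in transplant against adult (highest other 1) and 5394 in transplant against embryo (highest other 2).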

How the results depend on the processing

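Chosen after seeing the data were the runs with isolated zeros as missing, without small and ribosomal RNA genes, without cell cycle genes and without kinases in the ribosomal list. Of 724 results for named genes, 647 were called and 91 of these lost the call under some alternative. Many of these genes were chosen for large changes in the main fit. Over all genes, median-ratio scaling kept 5306 of 6699 calls in adult against embryo and 3154 of 3308 in teratoma against embryo. It kept 4063 of 5763 in teratoma against adult and 1739 of 2874 in transplant against teratoma. For transplant against adult and against embryo it kept 5171 of 5612 and 4307 of 5394. Only Hspa8 in adult against embryo reversed, to -0.13 with quantile normalization (adjusted p = 0.689); the cause was not tested. Of 120 list calls, 22 held with an estimated correlation, and 32 were lost under another alternative. The filter at a mean of 5 FPKM, which tests fewer genes, gave 4370 called genes in adult against embryo, 2084 in teratoma against embryo and 3720 in teratoma against adult. A log2 change of at least 1 left 1623 in transplant against teratoma. The teratoma and transplant positions on the axis were 0.376 and 0.538 with median-ratio scaling and 0.325 and 0.556 with a pseudocount of 0.1. They were 0.427 and 0.609 with quantile normalization and 0.371 and 0.562 without small and ribosomal RNA genes. Without cell cycle genes they were 0.357 and 0.532. The correlation of transplant against teratoma changes with adult against embryo ones was then 0.206. The cause of these shifts was not tested. Depth is unknown, so what it limits could not be assessed.

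Leaving out 1 library at a time, counts ran from 5951 (adult replicate 1) to 6708 (teratoma replicate 1) in adult against embryo, 2123 (teratoma replicate 2) to 3184 (transplant replicate 2) in teratoma against embryo, 4582 (teratoma replicate 2) to 6224 (embryo replicate 2) in teratoma against adult, 1524 (teratoma replicate 1) to 3285 (embryo replicate 2) in transplant against teratoma, 4570 (transplant replicate 1) to 6051 (embryo replicate 2) in transplant against adult and 4536 (transplant replicate 1) to 5379 (teratoma replicate 1) in transplant against embryo. The correlation of the changes ran from 0.215 (transplant replicate 3) to 0.284 (transplant replicate 1), the shared calls from 521 (teratoma replicate 2) to 783 (teratoma replicate 1), and the axis position from 0.347 (adult replicate 2) to 0.363 (adult replicate 3) for teratoma and 0.542 (transplant replicate 3) to 0.575 (transplant replicate 1) for transplant.

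Whether the replicate numbers pair the samples is not known, as the labels give only shared numbers. Deviations of libraries with the same number correlated at -0.0951 to 0.0956. Deviations from a group mean cancel within the group, so these values cannot decide on pairing. With the number as a block, 6551, 3009, 5531, 2466, 5398 and 5190 genes were called in adult against embryo, teratoma against embryo, teratoma against adult, transplant against teratoma, transplant against adult and transplant against embryo.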

Other observations

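Some factors that mark where in the body a muscle forms differed between the groups. Tcf21, a regulator of head muscle, was at 10.9 ± 2.31 in teratoma, 3.88 ± 0.806 in transplant, 0.116, 0 and 0 in the embryo libraries and 0, 0.142 and 0 in adult. It was higher in teratoma than in embryo by 3.50 (adjusted p = 1.88e-06). Tbx1, of pharyngeal mesoderm, was at 11.6 ± 2.04 in teratoma and 1.94 ± 0.545 in transplant (log2 change -2.10, adjusted p = 0.000727). Isl1 and Barx2 were higher in transplant than in adult by 2.48 and 2.90 (adjusted p at most 0.0003). Tbx15 was lower in teratoma than in embryo (log2 change -2.05, adjusted p = 0.000231). The list of position factors had 5 higher and 2 lower of 11 (5 and 3 adjusted over the list alone) in teratoma against embryo and was not called there (camera adjusted p = 0.25).

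Single signalling genes differed between the groups. Mstn, which encodes the muscle growth inhibitor myostatin, was at 15.8 ± 12.3 in embryo, 0.576 ± 0.334 in teratoma, 5.73 ± 1.47 in transplant and 0.113, 0.111 and 0 in adult, lower in teratoma than in embryo by 3.17 and higher in transplant than in teratoma by 2.09 (adjusted p = 0.00029 and 0.00531). The matrix gene Ctgf was higher in transplant than in teratoma by 2.52 (adjusted p = 8.92e-05). Among 22 targets of BMP and TGF-beta in transplant against teratoma, 7 passed as higher and 3 as lower (7 and 5 adjusted over the list alone), and the median log2 change was 0.23 (camera adjusted p = 0.0019, adjusted p = 0.147 with an estimated correlation). Sfrp2, a secreted Wnt antagonist, was lower in teratoma than in embryo by 2.97 (adjusted p = 0.000299). The list of 20 Wnt targets in teratoma against embryo held 1 higher and 9 lower (1 and 10 adjusted over the list alone), at a median log2 change of -0.67 and camera adjusted p = 0.00158 (adjusted p = 0.125 with an estimated correlation).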
